A study of Mus musculus with 12 samples.

How the data were processed

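Liver RNA of 12 samples from male mice (wild type or Lmna G609G knock-in, control or methionine-restricted diet, 3 arrays per group) was hybridised to Affymetrix Mouse Gene 1.0 ST arrays. Per the labels, total RNA was extracted with Trizol and RNeasy columns and biotin-labelled. The labels do not say that each array comes from a separate animal, so p values measure the spread between samples. The deposited values were linear intensities, whole numbers from 10 to 20042, on a common scale between arrays (medians 82 to 90). The method of background correction and scaling is not given in the sources used here. The log2 of the values was taken with no further scaling. Rounding to whole numbers gives steps of 0.0444 (log2) at 32 units, and 13.98% of gene values lay under 32 units, so small changes of dim genes are coarse.

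The table held 35512 probe sets. Of these, 21789 carried 1 gene symbol in the probe annotation, 1621 carried several and 12102 had none. For each gene the probe set with the highest mean over all arrays was used, which gave 19938 genes, 999 of them with more than 1 probe set. The Entrez identifier of 19856 genes matched the reference gene table, and 0 symbols changed through it. Probe sets of a named gene that gave other values are reported beside the gene.

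One linear model with the 4 group means was fitted to all 12 arrays in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation at its default settings. There were 8 residual degrees of freedom and 3.14 prior degrees of freedom. The contrasts were KI_CD minus WT_CD, KI_MR minus KI_CD, WT_MR minus WT_CD, KI_MR minus WT_MR and the interaction of diet with genotype. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within a contrast and a threshold of 0.05. An exact permutation test of 3 against 3 arrays cannot give a two-sided p under 0.1, so single genes were not tested that way. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

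Before the data were examined, 24 pathway and 11 cell type lists, the contrasts, the alternatives and the rule for named genes were written down. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 35 lists of a contrast, and again with an estimated correlation. The rotation test fry was added after the results were seen. Members were counted over all genes and adjusted over the list alone. The rule names, per comparison, the 8 largest rises and 8 largest falls among genes past the threshold without overlap of the groups, leaving out predicted loci. It further names up to 4 members with the smallest p per described list, and a set of progeria, bile acid and methionine genes. For the interaction, with 0 genes past the threshold by limma and 824 at an unadjusted p under 0.05, it takes the 4 each way with the smallest p. Members of lists named beyond the first 4, genes standing out in a single array and genes shared between contrasts were chosen after their values were seen.

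Correlations between contrasts were taken across genes, with a jackknife over arrays for the SE. Contrasts that share a group were set against 100 simulated data sets with the same spread and no effect. The fit was tested on simulated data made from the spread of these arrays, with 200 changed genes in each of 5 runs. It recovered 56.8% of changes of 0.5, 94.8% of 1, 98.8% of 2 and 100% of 4 (log2). Of 933 calls 57 were false (6.11%). The changed genes were drawn at random, and the noise was normal and independent between genes. A real gene with a wide spread can therefore miss the threshold at changes of these sizes. Of lists without a change 1.4% had a p under 0.05, and a shifted list was recovered in 5 of 5 runs. The members of these simulated lists were not correlated, whereas the estimated correlations of the real lists ranged from -0.01 to 0.74. The 1.4% therefore does not give the rate of false calls among real lists.

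The alternatives were quantile normalization, median centring, leaving out the dimmest 25% or 50% of genes, averaging the probe sets of a gene, testing all probe sets, a prior with intensity trend and robust estimation, array weights, a fit of the 6 compared arrays alone, replicate number as a block, a minimum log2 fold change of 1, and each array left out in turn. Gene-by-gene array weights were added after the data were seen, because the first weights put most of the weight on 1 array. The labels give no batch or date. The bounds for dim genes were added after the results were seen. Each sets the mean of the brighter group against that of the dim group, with every dim array taken at the higher of its own value and its lower quartile of gene levels. Probe sets without a single symbol were tested in a separate step and are given as counts.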

Results

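Liver transcript levels were measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, in male C57BL/6N mice of 110 days taken after 6 hours of fasting. The mice were wild type (WT) or homozygous for the Lmna G609G knock-in (KI), an allele used as a mouse model of Hutchinson-Gilford progeria. From 7 weeks of age they received a control diet (CD) or a diet restricted in methionine (MR). This gave 4 groups of 3 arrays each, named WT_CD, WT_MR, KI_CD and KI_MR. The median intensity ranged from 82 to 90 units between arrays. The number of arrays limits the precision of every value. Changes are log2 fold changes ± SE from 1 limma fit over 19938 genes, with n = 3 arrays per group, and adjusted p values come from that fit. The data hold no detection calls. Where a group mean lies below the lower quartile of gene levels of its arrays (5.49 to 5.67, log2), the log2 value is a difference of measured intensities, and a bound ("at least") is given beside it with dim arrays raised to that quartile.

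Lmna itself had a mean log2 level of 7.37 (SD 0.03) in WT_CD, 7.55 (SD 0.09) in WT_MR, 8.0 (SD 0.32) in KI_CD and 7.85 (SD 0.14) in KI_MR. Its change with the knock-in was 0.63 ± 0.13 on the control diet (limma adjusted p = 0.121) and 0.31 ± 0.13 on the restricted diet (adjusted p = 0.337), and neither passed over all genes. The knock-in is a point mutation that changes splicing of the lamin A message. The gene-level probe set cannot tell lamin A from progerin, so this level checks nothing about the genotype labels.

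KI_CD replicate 1 stood apart from the other arrays. Its mean correlation with the other 2 arrays of its group was 0.986 across genes, against 0.989 to 0.994 for the other 11 arrays. Against those 2 arrays, its male-biased genes had a median deviation of -1.47 (log2), its glutathione and NRF2 target genes 0.83, its cell cycle genes 0.75 and its amino acid response genes 0.69. Single genes differed by more, with Dmbt1 higher by 5.27, Gpnmb by 3.13 and Ccnd1 by 3.05, and Slco1a1 at -4.85.

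The first comparison asked what the knock-in changed in liver on the control diet. The largest rise and the 3 largest falls lay in genes whose liver levels differ between the sexes. The female-biased cytochrome P450 gene Cyp2b9 was 24.1-fold higher in KI_CD than in WT_CD (4.59 ± 0.47, limma adjusted p = 0.00653). The male-biased fatty acid elongase gene Elovl3 was lower (-4.56 ± 0.59, adjusted p = 0.0176). The male-biased omega-hydroxylase genes Cyp4a12b (-3.83 ± 0.40) and Cyp4a12a (-3.81 ± 0.42) were also lower, as was Serpina12, which encodes vaspin (-2.29 ± 0.24, adjusted p = 0.00653). Close paralogs such as Cyp4a12a and Cyp4a12b, or Cyp2b9 and Cyp2b13, can share signal on such arrays.

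In total 16 genes changed, 12 higher and 4 lower. The higher genes included the thyroxine-binding globulin gene Serpina7 (2.53 ± 0.24, limma adjusted p = 0.00634), the organic anion transporter gene Slco1a4 (2.13 ± 0.32), the acyltransferase gene Acnat2 (2.03 ± 0.29) and the transporter gene Flvcr2 (1.53 ± 0.23). Cyp2c39 (1.46 ± 0.18), Ildr2 (1.43 ± 0.19) and Tox (1.19 ± 0.17) were higher too. With each of the 12 arrays left out in turn, the call of Slco1a4 was lost in 9 fits, that of Flvcr2 in 8 and those of Acnat2 and Tox in 7 each. Ildr2 lost its call in 4 fits, Cyp2c39 in 1, and Cyp2b9 and Serpina7 in 0. The other 4 lay outside the rule for named genes and were picked after their values were seen: the citrate transporter gene Slc13a5 (1.07), the cold-inducible RNA-binding protein gene Rbm3 (0.71), angiotensinogen (Agt, 0.66) and the angiotensin II receptor gene Agtr1a (0.55). The 3 probe sets of Rbm3 gave 0.71, 0.72 and 0.68. All 16 genes had no overlap between the groups. Over all genes, 19.0% had none, against 10% by chance, and 2234 had an unadjusted p under 0.05.

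Of 35 gene lists, 11 passed in KI_CD against WT_CD by camera with a preset correlation, and 0 with an estimated one, where 2 had an unadjusted p under 0.05. The rotation test fry called 1 list. The male-biased liver genes fell, with a median of -1.96 and all 14 members below 0 (camera adjusted p = 1.59e-17; adjusted p = 0.244 with an estimated correlation; fry adjusted p = 0.0129). Over all genes 3 members were lower, and 12 were when adjusted over the list alone, among them the major urinary protein gene Mup21 (-2.36). The female-biased genes rose by a median of 0.70 (adjusted p = 7.25e-05, or adjusted p = 0.617 with an estimated correlation). Of these 12 genes only Cyp2b9 passed, over all genes and adjusted over the list alone; Fmo2 (1.12), Cyp17a1 (1.13) and Cyp2b13 (1.46, or at least 1.81-fold, and 0.90 without KI_CD replicate 1) did not.

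Lipid synthesis genes were lower as groups. The cholesterol synthesis list had a median of -0.27 with 18 of 20 members below 0 (camera adjusted p = 0.00376; adjusted p = 0.636 with an estimated correlation). Its first members Tm7sf2 (-0.82), Nsdhl (-0.78) and Sqle (-1.01) did not pass, and 0 of the 20 did over all genes or adjusted over the list alone. Without KI_CD replicate 2 Nsdhl was at -0.52 and Sqle at -0.65. The fatty acid synthesis list had a median of -0.36 with 17 of 20 below 0 (adjusted p = 0.00455; adjusted p = 0.636 with an estimated correlation). No member of it passed by limma either way, with Thrsp at -1.95, the malic enzyme gene Me1 at -1.09 and Elovl6 at -0.72, the last 2 at -0.72 and -0.44 without WT_CD replicate 2. Both calls ended without KI_CD replicate 2, with adjusted p = 0.492 for cholesterol and 0.268 for fatty acid synthesis, and without WT_CD replicate 2, with 0.110 and 0.101. The mean of the fatty acid synthesis list was -0.44, and was -0.27 and -0.28 without these arrays but -0.70 without KI_CD replicate 3 and -0.69 without WT_CD replicate 3; that of the cholesterol list went from -0.36 to -0.13 and -0.24.

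The nuclear lamina and envelope list was higher by a median of 0.11, with 13 of 14 members above 0 (camera adjusted p = 0.00376; adjusted p = 0.617 with an estimated correlation). Lmna passed only when adjusted over the list alone. Sun1 was at 0.33, Syne1 at 0.40 and the lamin A protease gene Zmpste24 at 0.23, each short of the threshold. A second probe set of Syne1 gave 0.15, and a second, dim one of Zmpste24 0.065. The p53 targets had a median of 0.14 (adjusted p = 0.00399; adjusted p = 0.636 with an estimated correlation), with Btg2 at 0.85 and Gadd45b at 1.11. The amino acid response genes had a median of 0.16 (adjusted p = 0.0122; adjusted p = 0.636 with an estimated correlation), with the glutathione-degrading enzyme gene Chac1 at 0.87. No p53 or amino acid response member passed by limma, over all genes or adjusted over the list alone. These 3 list calls moved with KI_CD replicate 1. Without it the nuclear lamina list had adjusted p = 0.0597 and the p53 list 0.340, with means going from 0.16 to 0.092 and from 0.30 to 0.15. For the amino acid response list the mean turned from 0.27 to -0.04 (adjusted p = 0.731), against 0.41 and 0.45 without KI_CD replicates 2 and 3.

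The acute phase genes were higher by a median of 0.19 (camera adjusted p = 3.37e-04; adjusted p = 0.636 with an estimated correlation), and none of the 20 passed by limma over all genes or adjusted over the list alone. Stat3 (0.64), Socs3 (0.62) and the serum amyloid P gene Apcs (0.99) came first, and a second, dimmer probe set of Socs3 stayed at 0.00. The mean of the list was 0.34, and ranged from 0.11 without WT_CD replicate 1 to 0.77 without WT_CD replicate 3, whose log2 levels of Saa1 (11.08) and Lcn2 (12.72) were high. The list mean was 0.14 without WT_CD replicate 2 and 0.18 without KI_CD replicate 2. Neither gene passed. Lcn2 was at 1.90, or 1.21 and 3.19 without WT_CD replicates 1 and 3. Saa1 was at -0.47, and turned to 1.49 without WT_CD replicate 3 and 0.30 without KI_CD replicate 3, against -1.48 and -1.41 without WT_CD replicates 1 and 2 and -1.18 without KI_CD replicate 2.

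The methionine cycle list was higher by a median of 0.14 (camera adjusted p = 0.0217; adjusted p = 0.636 with an estimated correlation). Adjusted over the list alone, the cystathionine gamma-lyase gene Cth was higher (0.78 ± 0.15) and the taurine synthesis gene Csad lower (-0.83), and neither passed over all genes. Interferon-stimulated genes were lower by a median of -0.25 (adjusted p = 0.0428), and the macrophage and Kupffer cell markers by -0.33 with 10 of 11 members below 0 (adjusted p = 0.0150); both had adjusted p = 0.636 with an estimated correlation. Examples were Irf7 at -0.63 (-0.36 without KI_CD replicate 1) and the Kupffer cell genes Vsig4 (-0.54) and C1qb (-0.51), which did not pass. These 3 calls were lost without single arrays. Leaving out KI_CD replicate 3 or WT_CD replicate 3 gave the methionine list adjusted p = 0.308 or 0.0809, quantile normalization 0.0840 and leaving out the dimmest 25% of genes 0.0867. The interferon list had 0.134 without KI_CD replicate 2, 0.0553 without WT_CD replicate 1, 0.374 without WT_CD replicate 3 and 0.0604 without WT_MR replicate 2, and 0.0663 with replicate number as a block. The macrophage list had 0.0988, 0.112 and 0.105 without KI_CD replicates 2 and 3 and WT_CD replicate 2, and its mean went from -0.30 to -0.19 without WT_CD replicate 2, -0.20 without KI_CD replicate 3 and -0.46 without KI_CD replicate 1.

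Genes of special interest in progeria and bile acid metabolism did not pass in KI_CD against WT_CD. The sterol 12-alpha-hydroxylase gene Cyp8b1 was at -1.72 ± 0.61 (limma adjusted p = 0.342), Cyp7a1, which encodes the rate-limiting enzyme of bile acid synthesis, at 0.27, the senescence marker Cdkn2a at -0.11, the growth factor gene Igf1 at -0.03 and the insulin-like growth factor binding protein gene Igfbp1 at 1.37. Igfbp1 was at 0.79 without KI_CD replicate 1, and Cyp7a1 at 0.11 without that array and 0.47 without KI_CD replicate 2. The count of 16 genes became 32 without KI_CD replicate 1 and 28 without WT_MR replicate 3. It fell to 10 without KI_MR replicate 1 and 2 without WT_CD replicate 1. The 16 genes kept their sign each time, which their lack of overlap between the groups fixes in advance. A limma fit of the 6 compared arrays alone called 0 genes, with 2734 at an unadjusted p under 0.05.

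**Figure D1:**
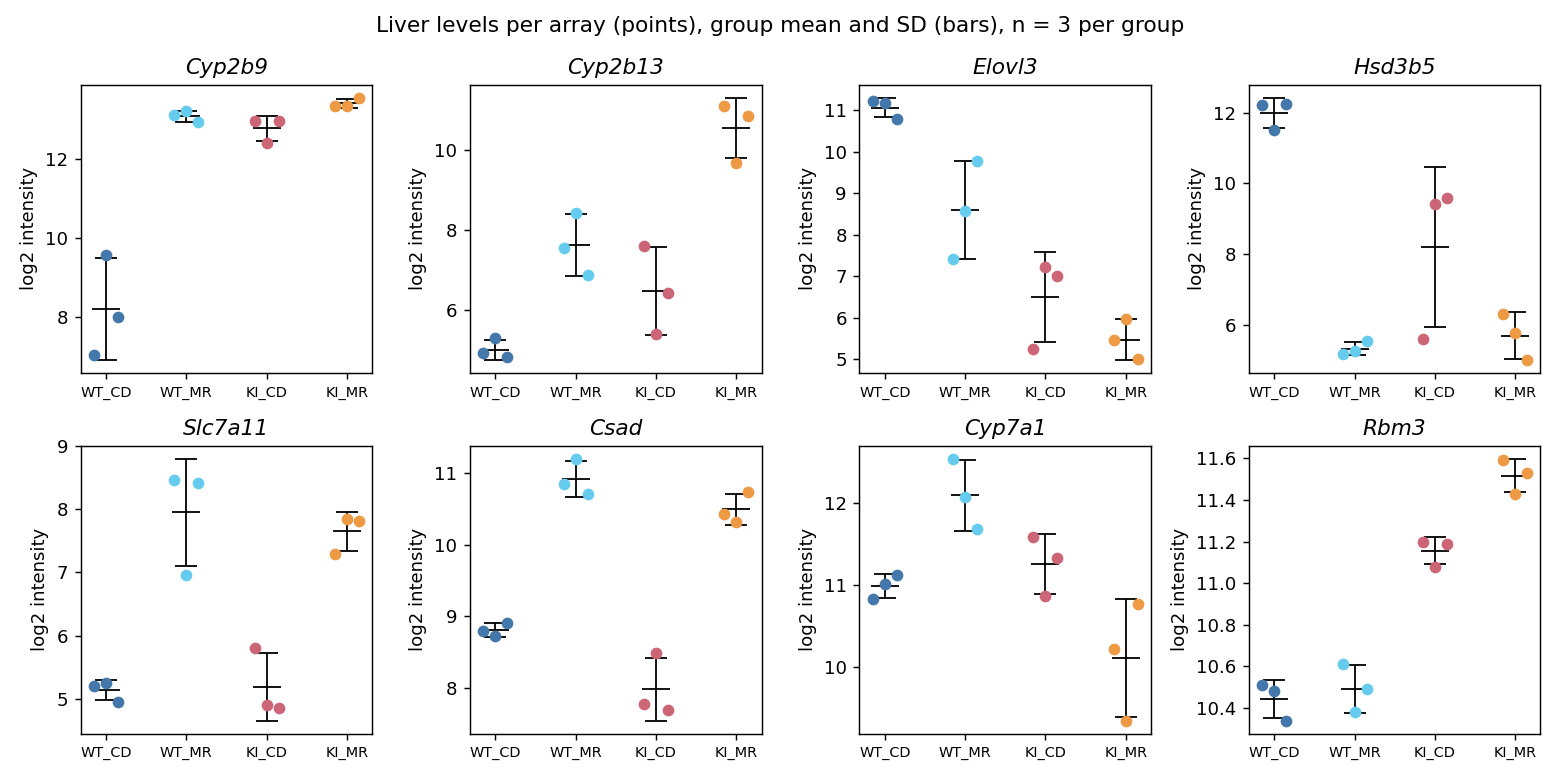
Log2 intensity of 8 genes (y axis) in the 4 groups (x axis), with 1 point per array and bars for the group mean and SD, n = 3 per group. Cyp2b9 rose by 4.59 with the knock-in on the control diet and by 4.89 with restriction in wild type, and Slc7a11 and Csad rose with restriction in both genotypes.

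The second comparison asked what methionine restriction changed in knock-in liver. The taurine synthesis gene Csad rose by 2.51 ± 0.20 (limma adjusted p = 0.00120) and the cystine transporter gene Slc7a11 by 2.46 ± 0.37, or at least 4.09-fold (adjusted p = 0.0317). The mitochondrial folate enzyme gene Aldh1l2 rose by 1.59 ± 0.17 and the lipoprotein receptor gene Vldlr by 1.68 ± 0.28. The largest rise was that of the female-biased Cyp2b13 (4.08 ± 0.54, adjusted p = 0.0193).

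Of 35 changed genes in KI_MR against KI_CD, 12 were higher and 23 lower. Further rises were those of the integrin gene Itga6 (1.33 ± 0.21), the female-biased transcription factor gene Cux2 (1.20 ± 0.15) and the peptide hormone gene Adm2 (0.83 ± 0.12). The largest falls were in the adhesion receptor gene Adgrf1 (-2.0 ± 0.18, limma adjusted p = 0.00140), complement C6 (-1.64 ± 0.27), the sulfatase gene Sulf2 (-1.52 ± 0.20), the lectin gene Clec2h (-1.50 ± 0.16) and Gpx6 (-1.48 ± 0.18). Slc13a5 fell by 1.34 (SE 0.14), the clock repressor gene Bhlhe41 by 1.09 (SE 0.17, at least 1.78-fold) and the periportal P450 gene Cyp2f2 by 1.04 (SE 0.09, adjusted p = 0.00120). Over all genes, 10.7% had no overlap between the groups, against 10% by chance. An unadjusted p under 0.05 was reached by 1551 genes.

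Camera with a preset correlation called 12 lists in KI_MR against KI_CD and 0 with an estimated one, where 4 had an unadjusted p under 0.05. The test fry called 0 lists, with 5 at an unadjusted p under 0.05. The amino acid response genes rose by a median of 0.44 (adjusted p = 6.12e-13; adjusted p = 0.359 with an estimated correlation). The methionine cycle list was not called (median -0.11, 12 of 18 below 0, adjusted p = 0.186), but camera looks for a shift in 1 direction. Adjusted over the list alone, 1 of its members was higher and 4 were lower. The fry test of change in either direction, which does not set a list against other genes, gave it an unadjusted p = 1.78e-06. Other lists, the female-biased and periportal ones among them, were also under 0.05 by that test. The value therefore does not set methionine cycle genes apart. In the amino acid response list 3 of 22 members rose over all genes (Aldh1l2, Slc7a11 and Vldlr) and 11 adjusted over the list alone. The asparagine synthetase gene Asns (2.38 ± 0.48, limma adjusted p = 0.106) and the amino acid transporter gene Slc7a5 (1.03) did not pass over all genes. The glutathione and NRF2 list rose by a median of 0.23 with 14 of 15 members above 0 (adjusted p = 1.59e-06; adjusted p = 0.359 with an estimated correlation). Its only member past the test was Slc7a11, over all genes and adjusted over the list alone, with Nqo1 at 0.74 (0.40 without KI_CD replicate 2) and Gclm at 0.23. The mean of the NRF2 list was 0.40, and was 0.61 without KI_CD replicate 1 and 0.26 without KI_CD replicate 2.

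The male-biased genes fell again, with all 14 members below 0 and a median of -1.0 (camera adjusted p = 1.22e-08; adjusted p = 0.359 with an estimated correlation). C6 was lower over all genes, and 6 members were adjusted over the list alone, among them Cyp4a12b (-2.01) and Cyp4a12a (-1.98). The female-biased genes rose by a median of 0.64 (adjusted p = 2.31e-06; adjusted p = 0.359 with an estimated correlation), with Cux2 and Cyp2b13 past the test over all genes and 4 of 12 adjusted over the list alone, Acot3 (1.40) and Fmo2 (1.22) included.

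The acute phase list fell by a median of -0.35 with 19 of 20 members below 0 (camera adjusted p = 2.84e-05; adjusted p = 0.516 with an estimated correlation). Orm2 (-3.46) and Lcn2 (-2.76) had the largest values, and by limma no member passed over all genes or adjusted over the list alone. Interferon-stimulated genes fell by a median of -0.25 (adjusted p = 0.00227; adjusted p = 0.456 with an estimated correlation), with 14 of 15 below 0 and Oasl1 at -0.46. The pericentral hepatocyte genes fell by a median of -0.23 (adjusted p = 0.00104; adjusted p = 0.359 with an estimated correlation). Adjusted over the list alone, 3 of its 9 members were lower: the glutamate transporter gene Slc1a2 (-0.57), the ammonium transporter gene Rhbg (-0.98) and Oat (-0.89).

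The cholesterol list rose by a median of 0.30 with 16 of 20 members above 0 (camera adjusted p = 4.05e-04; adjusted p = 0.581 with an estimated correlation). Adjusted over the list alone, Fdft1 was higher (0.42) and Ebp lower (-0.47), and neither passed over all genes. The fatty acid synthesis list rose by a median of 0.24 (adjusted p = 0.0157; adjusted p = 0.581 with an estimated correlation), with Me1 at 1.03, or 0.68 without KI_CD replicate 1. Without KI_CD replicate 2 the adjusted p was 0.469 for cholesterol and 0.594 for fatty acid synthesis, and without KI_CD replicate 1 it was 0.162 for the latter. Their means went from 0.26 and 0.22 to 0.031 and 0.048 without KI_CD replicate 2 and to 0.43 and 0.48 without KI_CD replicate 3, and that of fatty acid synthesis to 0.13 without KI_CD replicate 1.

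Bile acid transport genes rose by a median of 0.18 (camera adjusted p = 0.00109; adjusted p = 0.359 with an estimated correlation), with the export pump gene Abcc3 at 0.90 and Slco1a1 at -2.71 (-4.32 without KI_CD replicate 1). The cell cycle list fell by a median of -0.26 with 16 of 17 below 0 (adjusted p = 0.00130; adjusted p = 0.581 with an estimated correlation), with Cdk1 at -0.79 (-0.24 without KI_CD replicate 1). The unfolded protein response list fell by a median of -0.17 (adjusted p = 0.00187; adjusted p = 0.471 with an estimated correlation), and Pdia6 (-0.76) and Sdf2l1 (-0.89) were among 3 members lower adjusted over the list alone. These 3 calls ended without KI_CD replicate 1. The adjusted p was then 0.252 for bile acid transport, whose mean turned from 0.10 to -0.05, 0.852 for the cell cycle, whose mean shrank from -0.35 to -0.01, and 0.0865 for the unfolded protein response. The mean of the bile acid transport list also ranged from 0.06 without KI_MR replicate 1 and 0.07 without KI_MR replicate 3 to 0.19 without KI_MR replicate 2 and 0.21 without KI_CD replicate 3, and that of the cell cycle list was -0.56 without KI_CD replicate 2.

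Cyp7a1 was at -1.15 ± 0.32 (limma adjusted p = 0.272) and the stress hormone gene Fgf21 at -0.32 ± 0.43, neither past the test in KI_MR against KI_CD. Fgf21 turned to 0.27 without KI_CD replicate 1 and went to -0.59, -0.63, -0.52 and -0.14 without KI_CD replicates 2 and 3 and KI_MR replicates 1 and 3. The count of 35 genes rose to 94 without KI_CD replicate 1 and 69 without KI_MR replicate 2. It fell to 7, 8, 10 and 14 without KI_MR replicate 3, KI_CD replicate 3, KI_MR replicate 1 and KI_CD replicate 2 in turn. Without WT_MR replicate 1, WT_CD replicate 1 and WT_CD replicate 2 it was 19, 20 and 20. The 35 genes kept their sign each time, which is fixed in advance because their groups did not overlap. With median centring 18 genes changed, 8 higher and 10 lower, so the share of higher genes was 44.4% in place of 34.3%. A limma fit of the 6 compared arrays alone called 0 genes, with 1472 at an unadjusted p under 0.05.

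The third comparison asked what the same diet changed in wild-type liver. The male-biased steroid dehydrogenase gene Hsd3b5 fell at least 84.5-fold (-6.68 ± 0.83, limma adjusted p = 0.00686) and the female-biased Cyp2b9 rose 29.7-fold (4.89 ± 0.47, adjusted p = 0.00135). The cystine transporter gene Slc7a11 rose by 2.81 ± 0.37, or at least 5.07-fold (adjusted p = 0.00935), the quinone reductase gene Nqo1 by 2.21 ± 0.27, or at least 4.47-fold, and Csad by 2.11 ± 0.20. As groups, amino acid response, NRF2 target and cholesterol synthesis genes rose by camera with a preset correlation, and were not called with an estimated one (adjusted p = 0.0688, 0.0688 and 0.274).

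Of 65 genes changed in WT_MR against WT_CD, 42 were higher and 23 lower. Among the higher ones were Cyp2c38 (2.53 ± 0.40), the stress-inducible gene Gadd45b (2.41 ± 0.42, limma adjusted p = 0.0413), the monocarboxylate transporter gene Slc16a5 (2.31 ± 0.35) and the PPARA target Cyp4a14 (2.06 ± 0.26). Among the lower ones were Mup21 (-3.09 ± 0.46), C6 (-2.65 ± 0.27, adjusted p = 0.00192), Cyp4a12b (-2.40 ± 0.40), Adgrf1 (-2.26 ± 0.18), Serpina12 (-2.16 ± 0.24), Moxd1 (-1.97 ± 0.34, at least 3.05-fold) and Carmil1 (-1.68 ± 0.27). Without overlap between the groups were 11.5% of all genes, against 10% by chance. An unadjusted p under 0.05 was reached by 1633 genes.

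In WT_MR against WT_CD camera with a preset correlation called 9 lists and 0 with an estimated one, where 6 had an unadjusted p under 0.05. The test fry called 4 of them: the male-biased, female-biased, amino acid response and NRF2 lists. The male-biased genes fell by a median of -2.16, all 14 below 0 (adjusted p = 3.79e-25; adjusted p = 0.0688 with an estimated correlation; fry adjusted p = 0.0104). Over all genes 4 of them were lower (C6, Hsd3b5, Mup21 and Cyp4a12b), and all 14 were adjusted over the list alone. The female-biased genes rose by a median of 0.69 (adjusted p = 5.85e-10; adjusted p = 0.0688 with an estimated correlation; fry adjusted p = 0.0194). Cyp2b9 passed over all genes, and 7 of 12 adjusted over the list alone, with Cyp2b13 at 2.61 (at least 4.02-fold), Acot3 at 1.76 and Fmo2 at 1.47.

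The amino acid response genes rose by a median of 0.71 with 20 of 22 members above 0 (camera adjusted p = 5.19e-20; adjusted p = 0.0688 with an estimated correlation; fry adjusted p = 0.0194). Slc7a11, Vldlr (1.90) and Aldh1l2 (1.54) rose over all genes and 12 adjusted over the list alone, while Asns (2.57 ± 0.48, limma adjusted p = 0.0566) fell short over all genes. The NRF2 targets rose by a median of 0.72 with 14 of 15 above 0 (adjusted p = 3.77e-18; adjusted p = 0.0688 with an estimated correlation; fry adjusted p = 0.0179). Nqo1, Slc7a11 and the glutathione reductase gene Gsr (0.57) rose over all genes and 13 adjusted over the list alone, Ugdh (1.38) included.

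The cholesterol synthesis list rose by a median of 0.68, with all 20 members above 0 (camera adjusted p = 7.72e-15; adjusted p = 0.274 with an estimated correlation). Squalene synthase (Fdft1, 0.63 ± 0.11, limma adjusted p = 0.0462) passed over all genes and 13 members adjusted over the list alone, including Hmgcs1 (1.48), Hsd17b7 (0.92) and the sterol regulator gene Srebf2 (0.53). The fatty acid oxidation and PPARA list rose by a median of 0.43 (adjusted p = 1.14e-08; adjusted p = 0.390 with an estimated correlation), with Cyp4a14 past the test over all genes and 6 of 23 adjusted over the list alone. Those 6 included the fatty acid translocase gene Cd36 (2.15), Pdk4 (1.90) and Fgf21 (1.70 ± 0.43, adjusted p = 0.173).

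The fatty acid synthesis list fell by a median of -0.22 with 18 of 20 below 0 (camera adjusted p = 6.40e-04; adjusted p = 0.550 with an estimated correlation), and adjusted over the list alone its regulator gene Srebf1 (-0.98) was lower, with 0 members past limma over all genes. Without WT_CD replicate 2 its adjusted p was 0.0792 and its mean -0.19, against -0.60 without WT_CD replicate 3. The xenobiotic list rose by a median of 0.15 (adjusted p = 0.0176; adjusted p = 0.149 with an estimated correlation), with Cyp2b10 (0.63) past the test only when adjusted over the list alone. It had adjusted p = 0.0682 without WT_CD replicate 3 and 0.0753 without the dimmest 25% of genes. The clock list fell by a median of -0.22 (adjusted p = 0.0305; adjusted p = 0.550 with an estimated correlation), with Bhlhe41 (-1.30 ± 0.17, at least 1.99-fold) lower over all genes and alone among 15 when adjusted over the list alone. That call ended without WT_CD replicate 3, WT_MR replicate 2 or WT_MR replicate 3 (adjusted p = 0.0941, 0.112 and 0.176), and with replicate number as a block (0.0749), and the mean of the list was -0.10 without WT_MR replicate 3.

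Cyp7a1 was at 1.11 ± 0.32 in WT_MR against WT_CD (limma adjusted p = 0.256). The count of 65 genes became 199 without KI_CD replicate 1, which is not one of the arrays compared, and fell to 17 without WT_CD replicate 1, 18 without WT_MR replicate 1, 27 without WT_MR replicate 2 and 38 without WT_CD replicate 3. The 65 genes kept their sign each time, which is fixed in advance because their groups did not overlap. A fit of the 6 compared arrays alone called 131 genes.

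The fourth comparison asked how the genotypes differed on the restricted diet. The retinaldehyde dehydrogenase gene Aldh1a1 was lower in KI_MR than in WT_MR (-1.43 ± 0.12, limma adjusted p = 9.57e-04) and the cold-inducible Rbm3 higher (1.02 ± 0.08, adjusted p = 9.57e-04). The male-biased Cyp4a12a (-3.85 ± 0.42) and Cyp4a12b (-3.44 ± 0.40) were lower, as on the control diet. Cyp7a1, the gene of the rate-limiting enzyme of bile acid synthesis, was lower as well (-1.98 ± 0.32, adjusted p = 0.0314). As a group, cholesterol synthesis genes were lower by camera with a preset correlation, but not with an estimated one (adjusted p = 0.730).

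Of 94 changed genes in KI_MR against WT_MR, 52 were higher and 42 lower. The higher ones included Cyp2b13 (2.93 ± 0.54, limma adjusted p = 0.0486), Acnat2 (2.0 ± 0.29), the lipogenic regulator gene Srebf1 (1.24 ± 0.21, adjusted p = 0.0401), Cyp2c37 (1.12 ± 0.20), the second cold-inducible gene Cirbp (1.11 ± 0.17), Nrbp2 (1.05 ± 0.16) and Shroom1 (0.94 ± 0.16). The lower ones included Nat8f5 (-2.43 ± 0.44, at least 4.79-fold), Keg1 (-2.38 ± 0.36), Nat8 (-1.93 ± 0.24) and Aldh1a7 (-1.60 ± 0.22). The other probe sets of Rbm3 gave 1.14 and 1.07. Groups did not overlap in 16.3% of all genes, against 10% by chance. At an unadjusted p under 0.05 there were 2818 genes.

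Camera with a preset correlation called 8 lists in KI_MR against WT_MR and 0 with an estimated one, where 2 had an unadjusted p under 0.05. The test fry called 0 lists, with 7 at an unadjusted p under 0.05. The cholesterol synthesis list was lower by a median of -0.83 with 18 of 20 members below 0 (adjusted p = 6.31e-10; adjusted p = 0.730 with an estimated correlation). Mevalonate diphosphate decarboxylase (Mvd, -1.12 ± 0.21, limma adjusted p = 0.0490) passed over all genes and 16 members adjusted over the list alone, including Nsdhl (-1.19), Ebp (-0.46) and Hsd17b7 (-0.84). The fatty acid oxidation and PPARA list was lower by a median of -0.40 with 21 of 23 below 0 (adjusted p = 2.55e-05; adjusted p = 0.730 with an estimated correlation). Over all genes 0 of its members passed by limma and 9 did adjusted over the list alone, among them the carnitine carrier gene Slc25a20 (-0.72), Cpt2 (-0.56), Fgf21 (-1.65 ± 0.43) and Ppara (-0.39). Without WT_MR replicate 2 the mean of this list shrank from -0.50 to -0.32.

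The male-biased genes were lower by a median of -0.51 with 13 of 14 below 0 (camera adjusted p = 0.00184; adjusted p = 0.730 with an estimated correlation). Cyp4a12a and Cyp4a12b passed over all genes, and 4 adjusted over the list alone, Elovl3 (-3.11 ± 0.59, at least 7.64-fold, limma adjusted p = 0.0510) included. The female-biased genes were higher by a median of 0.44 (adjusted p = 0.0106; adjusted p = 0.730 with an estimated correlation), with Cux2 (0.89) and Cyp2b13 past the test over all genes and adjusted over the list alone. Clock genes were higher by a median of 0.34 with 13 of 15 above 0 (adjusted p = 0.00184; adjusted p = 0.730 with an estimated correlation), among them Per1 (1.18) and Arntl (0.72, or 0.45 without WT_MR replicate 1), though none passed by limma over all genes or adjusted over the list alone. Interferon-stimulated genes were lower by a median of -0.27 (adjusted p = 0.0164; adjusted p = 0.730 with an estimated correlation), with Stat2 at -0.39 (-0.24 without KI_MR replicate 3). These 4 calls ended without WT_MR replicate 3, with adjusted p = 0.237 for the male-biased, 0.138 for the female-biased, 0.138 for the clock and 0.579 for the interferon list. The means of the clock and interferon lists were then 0.18 and -0.14.

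NRF2 targets were lower by a median of -0.27 with 14 of 15 below 0 (camera adjusted p = 0.0164; adjusted p = 0.851 with an estimated correlation). Of these, 2 passed adjusted over the list alone, Ugdh (-1.03) and Gstm2 (-0.89), and 0 by limma over all genes. The hepatocyte markers were higher by a median of 0.06, all 10 above 0 (adjusted p = 0.0113; adjusted p = 0.703 with an estimated correlation). The NRF2 call ended without KI_MR replicate 2 (adjusted p = 0.271) or WT_MR replicate 3 (0.456), and the hepatocyte call without WT_MR replicate 2 (0.0855), after quantile normalization (0.386) and without the dimmest 25% of genes (0.0790).

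Cyp8b1 was at -2.35 ± 0.61 in KI_MR against WT_MR and did not pass (limma adjusted p = 0.115). The count of 94 genes rose to 226 without KI_CD replicate 1 and 157 without WT_MR replicate 3. It fell to 57, 50, 30 and 21 without KI_CD replicate 2, WT_CD replicate 1, WT_CD replicate 2 and KI_MR replicate 1 in turn. Without WT_MR replicate 1, WT_MR replicate 2 and KI_MR replicate 3 it was 12, 3 and 3. All 94 genes kept their sign, which is fixed in advance because their groups did not overlap. With median centring 58 genes changed, 26 higher and 32 lower, so the share of higher genes was 44.8% in place of 55.3%. A fit of the 6 compared arrays alone called 15 genes, and a fit with replicate number as a block 177.

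**Figure D2:**
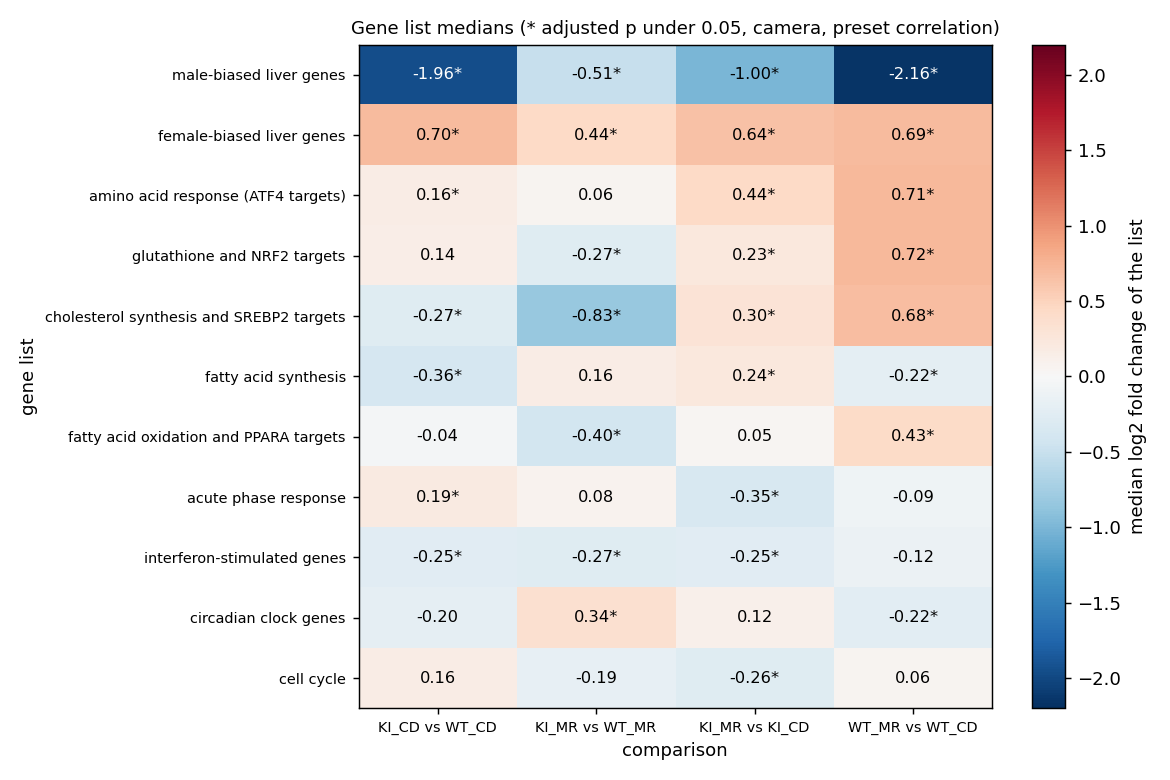
Median log2 fold change of 11 of the gene lists (y axis) in the 4 comparisons (x axis), with the colour and the printed number giving the median and a star an adjusted p under 0.05 by camera with a preset correlation. With an estimated correlation camera called 0 lists in each comparison (2, 4, 6 and 2 at an unadjusted p under 0.05 in KI_CD against WT_CD, KI_MR against KI_CD, WT_MR against WT_CD and KI_MR against WT_MR). The male-biased median was -1.96, -0.51, -1.0 and -2.16 in the order drawn, and the cholesterol median went from 0.68 with the diet in wild type to -0.83 for the knock-in on the restricted diet (adjusted p = 0.274 and 0.730 by camera with an estimated correlation).

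Whether the diet acted differently in the 2 genotypes was tested as an interaction, the diet effect in knock-in minus that in wild type. By limma 0 genes passed, with 824 at an unadjusted p under 0.05 and a smallest adjusted p of 0.293. Those 824 are a share under 0.05 of the 19938 genes, no more than tests without an effect would give. The genes with the smallest p are given as values only: Serpina7 (-2.33 ± 0.33), Slc13a5 (-1.26), Cyp2b9 (-4.25), Aldh1a1 (-1.01), Serpina12 (2.01), Slc17a8 (1.72), coagulation factor F11 (0.88) and Tmem267 (1.40). Cyp2b9 was already high in KI_CD (12.79, against 8.20 in WT_CD), and ended at similar levels in KI_MR (13.43) and WT_MR (13.09). For Cyp7a1 the value was -2.26 ± 0.46 (adjusted p = 0.652). Without KI_CD replicate 3, KI_MR replicate 2 or WT_CD replicate 2 the count was 1, 1 and 3.

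As groups, 9 lists differed between the diet effects by camera with a preset correlation, and 0 with an estimated correlation (smallest adjusted p = 0.566, with 1 list at an unadjusted p under 0.05) or by fry (0 lists at an unadjusted p under 0.05). The diet effect on fatty acid synthesis genes was higher in knock-in by a median of 0.45, with Srebf1 at 1.19 and Thrsp at 2.33. On cholesterol genes it was lower by a median of -0.39, and on PPARA targets by -0.35, with Cyp4a14 at -1.62 and Fgf21 at -2.02. On NRF2 targets it was lower by a median of -0.44, with Nqo1 at -1.47. Nqo1 was dim in WT_CD, and no bound was set for interaction values. On male-biased genes the diet effect was less negative by a median of 0.96, with Mup21 at 2.11. These genes started lower in KI_CD than in WT_CD, which leaves less room for a fall. Hsd3b5 went from 11.99 to 5.31 in wild type and from 8.20 to 5.69 in knock-in, both ending near the lower quartile of gene levels. A smaller fall in knock-in therefore need not mean a weaker action of the diet. KI_CD replicate 1 moved with these lists: without it the means went from -0.56 to -0.36 for PPARA targets, from -0.51 to -0.30 for NRF2 targets and from 1.12 to 0.61 for male-biased genes. The cholesterol mean went from -0.39 to -0.22 without KI_CD replicate 3 (adjusted p = 0.0643) and to -0.62 without KI_CD replicate 2.

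The diet effects of the 2 genotypes, which share no array, were compared across genes. Called in both were 11 genes, all in the same direction. Csad, Slc7a11, Aldh1l2, Vldlr and Mei4 rose in both, where 0.0253 shared genes would be found for independent calls. Adgrf1, C6, Clec2h, Bhlhe41, Itih5 and Olfm3 fell in both, against 0.0265. The correlation of the log2 fold changes was 0.453 (jackknife SE 0.189) across genes, which are not independent replicates, against -0.00110 in data simulated without a diet effect. It ranged from 0.34 without KI_CD replicate 2 to 0.55 without KI_CD replicate 1. The share of genes with the same sign was 56.1%.

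**Figure D3:**
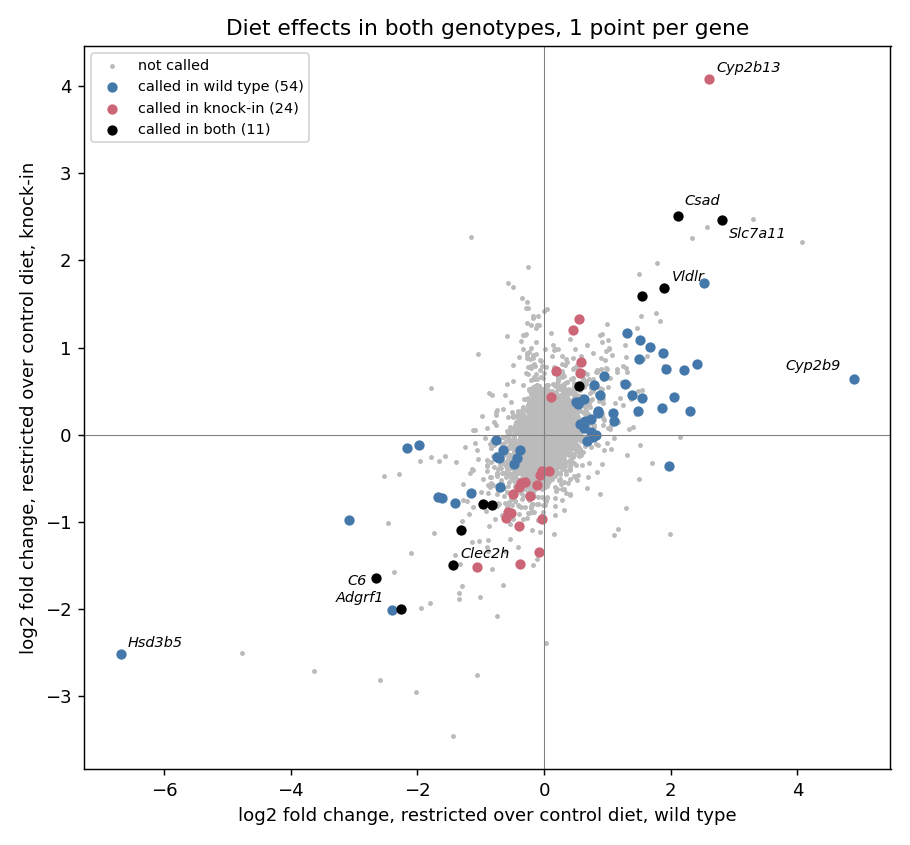
Log2 fold change of restricted over control diet in wild type (x axis) and in knock-in (y axis), 1 point per gene, with 54 genes called in wild type alone in blue, 24 in knock-in alone in red and 11 in both in black. Csad and Slc7a11 rose and Adgrf1 and C6 fell in both genotypes. Being called in 1 genotype alone does not show a difference between them. The interaction called 0 genes by limma, with 824 at an unadjusted p under 0.05, a share under 0.05 of all genes.

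Whether restriction moved the genes of the knock-in back towards wild type was asked next. Of the 16 genes changed by the knock-in on the control diet, only Slc13a5 was called in KI_MR against KI_CD, in the opposite direction (1.07, then -1.34). In the restricted knock-in livers the 16 genes kept a median of 118% of the knock-in difference relative to WT_CD, ranging from -25.2% to 164%. Data simulated with no diet effect gave 85.3% (82.8% to 88.0%). Their noise was independent between genes, and each simulated set called its own genes. That narrow range is therefore not the spread of a median over these 16 genes, which may move together. It does not show that 118% lies beyond what no diet effect would give. Of the 16, 5 moved against the knock-in difference and 11 moved further along it. The correlation across genes of the knock-in effect with the diet effect in knock-in was 0.00525 (jackknife SE 0.239). The shared KI_CD arrays alone gave -0.50 in simulated data. It was -0.17 without KI_CD replicate 2, 0.08 without KI_MR replicate 2 and -0.0846 without KI_CD replicate 1.

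The knock-in effect on the control diet and the diet effect in wild type overlapped in 6 genes, all in the same direction. Cyp2b9, Cyp2c39, Serpina7 and Slco1a4 rose and Cyp4a12b and Serpina12 fell with either, against 0.0253 and 0.00461 genes for independent calls. Data simulated without effects gave 0, but calls are rare in such data. These figures do not show how many calls the WT_CD arrays make common where genes do change. Both effects use the WT_CD arrays, which alone gave a correlation of 0.50 in simulated data, beside 0.485 measured; the covariance was 0.0118 simulated and 0.0237 measured. The knock-in effects on the 2 diets share no array and had a correlation of 0.489 across genes, with 70.2% of genes of the same sign. Acnat2 and Rbm3 were higher and Cyp4a12a and Cyp4a12b lower in the knock-in on both diets.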

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

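The tests that weigh the sex-biased genes, the counts over other splits of the samples and fry were chosen after the results were seen. The interaction contrast put 9 lists past the threshold by camera with a preset correlation of 0.01, each a difference of the diet effect between the genotypes. Its median was -0.39 for cholesterol synthesis (adjusted p = 4.24e-05), 0.45 for fatty acid synthesis (7.72e-07), -0.35 for fatty acid oxidation and PPARA targets (3.97e-06) and -0.18 for the methionine cycle (0.0149). It was -0.44 for NRF2 targets (4.22e-05), -0.11 for the acute phase response (0.0376), 0.96 for male-biased genes (8.53e-08), 0.30 for clock genes (6.20e-04) and -0.30 for the cell cycle (1.72e-04). With an estimated correlation none had an adjusted p under 0.566 (1 list at an unadjusted p under 0.05), and fry called 0 lists, also at an unadjusted p. For the male-biased list the lower levels in KI_CD left less room for a fall, so its difference need not mean a weaker action of the diet.

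Single arrays ended several of these calls. The adjusted p of the cell cycle list was 0.296 without KI_CD replicate 1, where its mean went from -0.45 to -0.11, and that of the cholesterol list 0.0643 without KI_CD replicate 3, with its mean going from -0.39 to -0.22. The methionine cycle list had 0.235, 0.0907 and 0.197 without KI_CD replicate 3, KI_MR replicate 1 and WT_MR replicate 3. The acute phase list had 0.317, 0.373, 0.557, 0.257 and 0.981 without KI_CD replicate 2, KI_MR replicate 1, WT_CD replicate 1, WT_CD replicate 2 and WT_MR replicate 3, and 0.0604 with replicate number as a block. Its mean, -0.38 in all arrays, was -0.22, -0.15, -0.18 and -0.084 without KI_CD replicate 2, WT_CD replicate 1, WT_CD replicate 2 and WT_MR replicate 3, but -0.81 and -0.59 without WT_CD replicate 3 and WT_MR replicate 2. The mean of the clock list went from 0.38 to 0.22 without KI_CD replicate 1, and to 0.22 without WT_MR replicate 3.

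Probe sets that carry no single gene symbol, which the gene comparisons do not use, held changes too. By limma 9 passed in KI_CD against WT_CD, 5 in WT_MR against WT_CD and 5 in KI_MR against WT_MR, of 13723 tested.

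The male-biased genes were lower, and female-biased genes higher, with the knock-in on the control diet and with restriction in knock-in and wild type by camera with a preset correlation, but not with an estimated one (adjusted p = 0.244, 0.359 and 0.0688 for male-biased and 0.617, 0.359 and 0.0688 for female-biased genes). The tables argue against animals of different sex between the groups, since the mean of 3 Y-linked genes varied over a range of 0.576 (log2) between arrays. They argue against fewer hepatocytes, whose markers had a lowest median of -0.032 over these 3 comparisons. They argue against array scaling through the array medians, which lay close together (82 to 90 units). The weakest mean of the male-biased list was -1.17 after quantile normalization, a step that could move it little in arrays so close in scale. A general loss of growth hormone signal is argued against by Igf1, whose lowest change was -0.19 ± 0.10. A changed pattern of growth hormone pulses, lower androgen levels, or smaller and leaner animals may still underlie the change, and none of these was tested.

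Other splits of the 6 arrays of each comparison into 3 and 3 were counted. In each of the 4 comparisons 1 of the 10 splits, the real one, called the most genes by limma: 16 against at most 2 in another split for KI_CD and WT_CD, 35 against 0 for KI_MR and KI_CD, 65 against 0 for WT_MR and WT_CD, and 94 against 3 for KI_MR and WT_MR. With 10 splits no share under 0.05 can be reached. For the interaction, 100 of 100 splits of the diet labels within genotypes gave at least the 0 genes of the real one by limma, which any split must and which decides nothing. At an unadjusted p under 0.05, 48 of 100 splits gave as many as the real 824 genes, the highest other being 3129. Exchanging diet labels within genotypes also carries the diet effect itself into the contrast or into the spread. These splits are thus no measure of chance for the interaction, and this share decides nothing either way. The real count is itself a share under 0.05 of all genes, no more than tests without an effect would give. The highest other count of called genes, 241, came from the split that exchanges the diet labels of all wild-type arrays. By construction that contrast is the sum of both diet effects, so the structure of the samples it points to is the diet. For the correlation of the diet effects, 2 of 100 splits, the real one included, gave a value as high as the real 0.453. The highest other value was 0.470. That share lies under 0.05, but another split was higher and the test was chosen after the results were seen. Chance is thus made less likely and is not excluded.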

How the results depend on the processing

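The gene-by-gene array weights and fry were chosen after the results were seen, the other alternatives before. Of the alternative values of named genes 4082 kept direction and side of the threshold, 413 lost the call, 128 gained one and 9 reversed. For called lists these were 737, 143, 0 gained and 2 reversed, and for counts and correlations 177 stayed within their bounds, 41 were lower, 20 higher and 3 moved from 0. The cause was not tested except where the alternative's own construction (fewer genes, fewer arrays, a fold minimum) gives it.

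For KI_CD against WT_CD (16 genes), leaving out the dimmest 25% of genes gave 31, the intensity trend with robust prior 26, array weights 168 and gene-by-gene weights 138. For KI_MR against KI_CD (35), median centring gave 18, the array weights 130, gene-by-gene weights 126, the minimum of 1 (log2) 15 and all probe sets 18. For WT_MR against WT_CD (65) the array weights gave 2204, gene-by-gene weights 564 and the minimum 37. For KI_MR against WT_MR (94), median centring gave 58, the array weights 4612, gene-by-gene weights 1514, the minimum 20 and all probe sets 51. The array weights put 16.7 on WT_MR replicate 1 and the gene-by-gene weights 3.88. The lowest were those of WT_MR replicate 3 (0.291 and 0.354), KI_CD replicate 1 (0.389 and 0.455) and WT_MR replicate 2 (0.397 and 0.511). Limma on the 6 compared arrays alone gave 0, 0, 131 and 15 genes in this order, with 2734, 1472, 1715 and 2475 at an unadjusted p under 0.05.

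The labels give no batch, and replicate numbers were not taken to pair the arrays. After removing group means, 9 of 18 pairs of the same number had a correlation over 0.1 (range -0.06 to 0.24). Their mean was 0.0961, against -0.0486 for other pairs, and 7 of 12 arrays correlated best with one of their own number. A structure shared by arrays of the same number therefore stays open. With number as a block the counts were 19, 34, 74 and 177, and 0 for the interaction. Of the 16, 35, 65 and 94 genes called without the block, 12, 26, 56 and 90 were called again.

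Leaving out 1 array at a time gave counts from 2 to 32 for KI_CD against WT_CD, 7 to 94 for KI_MR against KI_CD, 17 to 199 for WT_MR against WT_CD, 3 to 226 for KI_MR against WT_MR and 0 to 3 for the interaction, the highest of the first 4 without KI_CD replicate 1. Where this leaves a group of 2, the spread of the other groups is shared with it. Lists called ranged from 4 to 11 for KI_MR against WT_MR (8 in all arrays) and from 8 to 14 for the interaction (9).

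With an estimated correlation camera called 0 lists in each of the 5 contrasts (2, 4, 6, 2 and 1 at an unadjusted p under 0.05), and fry called 1, 0, 4, 0 and 0 (4, 5, 7, 7 and 0 unadjusted).

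These values reversed. Fgf21 in KI_MR against KI_CD (-0.32) was 0.093 with array weights, 0.080 with gene-by-gene weights and from -0.63 to 0.27 with arrays left out. Igf1 in KI_CD against WT_CD (-0.03) was 0.019 with either weighting and from -0.090 to 0.037 with arrays left out, and Saa1 (-0.47) from -1.48 to 1.49. The mean of the amino acid response list in KI_CD against WT_CD ranged from -0.041 to 0.45. That of the cell cycle list in KI_MR against KI_CD ranged from -0.56 to -0.0087, where the direction given by camera turned without KI_CD replicate 1.

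Signal near background limits the dim genes, where whole-number rounding adds steps of 0.0444 (log2) at 32 units.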

Other observations

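The noise test, the cell type test and the chaperone test of this part were chosen after the results were seen; the tests of hybridisation, Rbm3 and shared direction were written before their results. The bile acid synthesis list was not called in any contrast (lowest camera adjusted p = 0.219), where camera looks for a shift in 1 direction. The fry test of change in either direction does not set a list against other genes. Its unadjusted p ranged from 5.74e-07 (KI_MR against WT_MR) to 0.0188 (interaction). The female-biased list was also under 0.05 by this test in every contrast, so these values do not set bile acid genes apart. With the knock-in on the control diet the 14 synthesis genes had a median of -0.04, and adjusted over the list alone 2 were higher and 3 lower, among them Cyp2c70 (0.62 ± 0.15), which makes muricholic acids, and Cyp7b1 (-2.18 ± 0.53), which encodes the oxysterol 7-alpha-hydroxylase of the alternative pathway and is male-biased. In wild type, restriction raised the oxysterol hydroxylase gene Cyp39a1 (1.68 ± 0.27, limma adjusted p = 0.0297) and the export pump gene Abcc4 (1.49 ± 0.21, adjusted p = 0.0156), and lowered the sterol carrier gene Scp2 (-0.70 ± 0.12, adjusted p = 0.0462). The interaction of Abcc4 (-1.22 ± 0.30) did not pass (adjusted p = 0.966).

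Neither zonation list was called between the restricted groups (camera adjusted p = 0.168 for pericentral and 0.463 for periportal genes), but 1 member of each was lower. The pericentral ammonium transporter gene Rhbg (-1.42 ± 0.23, limma adjusted p = 0.0314) and the periportal Cyp2f2 (-0.87 ± 0.09, adjusted p = 0.00486) were the 2, lower in KI_MR than in WT_MR. For these lists the fry test of change in either direction gave unadjusted p = 1.74e-05 (pericentral) and 4.34e-06 (periportal). Hepatocyte, neutrophil and stellate cell markers were also under 0.05 by this test, which does not set a list against other genes. The values therefore do not set zonation genes apart. With restriction in knock-in the methionine cycle gene Bhmt was at -1.43 ± 0.33 (adjusted p = 0.159), a second probe set gave -1.52 and another, dimmer one -0.55.

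KI_CD replicate 1 stood apart from its group, with higher Asns (11.11 against 8.57 and 9.11) and lower Hsd3b5 (5.59 against 9.43 and 9.58). In 14 of 24 pathway lists the median deviated beyond the central 95% of matched random lists, so noise independent between probe sets does not alone account for its deviations. The random lists were drawn gene by gene, and the other arrays were not tested in this way. Lists of correlated genes can deviate so in any array, so the count does not show why this one stands apart. More cells of all other types alike stay open: macrophage markers deviated by 0.41 and endothelial markers by 0.09 (medians), but in 3 of the 11 other arrays the means of these markers moved apart by as much. A noisier hybridisation stays open too, as the relative deviation of the dimmest 25% of genes was 0.815 times that of the brightest 25%, just above the bound of 0.8 set for excluding it. A gain of macrophages and stellate cells alone (stellate markers deviated by 0.39), or a liver with a stress or regenerative response, is a candidate explanation that was not tested.

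The cold-inducible genes Rbm3 (0.71 and 1.02 on the control and restricted diet) and Cirbp (0.56 and 1.11) were higher in knock-in livers, Cirbp short of the threshold on the control diet. Array scaling is argued against by the smaller Rbm3 value of 0.69 after quantile normalization, though arrays already close in scale left that step little room. With each array left out the lowest Rbm3 value was 0.66, but the gap between the groups fixed in advance that it would stay high. On the control diet the lowest knock-in level was 11.08 and the highest wild-type level 10.51, and on the restricted diet they were 11.43 and 10.61. The Rbm3 difference thus does not rest on 1 array. A lower body temperature may be behind it: a list of 18 heat shock chaperones, written after the data were seen, had medians of -0.21 and -0.37 with 16 of 18 below 0 on both diets (larger p = 0.00142 by limma camera with a preset correlation). With an estimated correlation limma camera gave p = 0.159 and p = 0.0474, and by limma 0 members passed on either diet (6 and 9 at an unadjusted p under 0.05). The test leaves this open, also because the list moved without Rbm3 in WT_MR against WT_CD, with a median of 0.21, 1 of 18 below 0 (p = 9.99e-06 by limma camera with a preset correlation, p = 0.0636 with an estimated one) and Rbm3 at 0.05.

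A hypothesis that knock-in and restriction push the liver transcriptome along 1 shared direction was set against 100 splits of the diet labels and their mirrors. The correlation across genes of the average knock-in effect with the average diet effect was 0.284, and 21 of 200 values were as high, the highest other being 0.463, so the hypothesis was not borne out. The value was 0.217 without the sex-biased lists and 0.174 without KI_CD replicate 1.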
